A study of Mus musculus with 9 samples.

How the data were processed

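RNA was measured in pieces of spinal cord from mice at postnatal day 6 that carried a GAD65-GFP genotype, in which green fluorescent protein marks cells that use the promoter of the GABA-synthesising enzyme GAD65. Each of 3 animals gave a dorsal, an intermediate and a ventral piece, so that 9 arrays fell into 3 regions of 3. Per the labels' protocols, RNA was extracted with a kit, 500 ng of total RNA was converted to biotin-labelled cRNA with an Affymetrix 3' in vitro transcription kit, and the fragmented cRNA was hybridised. The labels mention no sorting of fluorescent cells, and the values are treated here as those of whole tissue pieces.

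The deposited table holds a value for each probe set and array, and the authors' deposited values were taken to be on a log2 scale because they run only from 2.146 to 16.27. No label states the scale, and the method by which the authors summarised, normalised or floored the probe signals is not given in the sources used here. Every fold change below rests on that reading of the scale. Between 35.97% and 36.26% of the probe sets of an array stood at the lowest value of the table, 2.146, or within 0.01 of it, which is called the floor, and array medians ran from 3.66 to 3.752. A probe set at the floor on all 3 arrays of a region has only a bound there, so a difference from such a region is given as a fold of at least that size. Many probe sets also carried identical values on several arrays: 2277 genes had 3 identical values above the floor within some region, 974 genes stood at the floor on all arrays of some region, and 6713 had 9 distinct values above the floor (tolerance 1e-06 for a tie and 0.01 for the floor). Identical values make a spread look smaller than it was, and the effect of leaving such genes out is given in the closing part. The number of arrays limits the precision, and the spread left after region and animal are fitted is estimated from 4 residual degrees of freedom.

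Probe sets were named through the platform annotation. Of 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had no entry in that annotation; the latter 2 kinds were named by no gene. A current gene table matched 34741 of the single-symbol probe sets by their Entrez number and changed 0 symbols. Each of the 18193 genes was represented by its brightest single-symbol probe set, by the mean over all arrays. Genes were kept when that mean reached the 30th percentile of all probe set means, 2.14606, which lies barely above the lowest value of 2.14597. This removed 4234 genes, all of them at the floor on all 9 arrays, and left 13959, of which 394 were also at the floor on all arrays. The arrays hold no genomic coordinates, so none are given.

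Differences were tested with limma 3.58.1 in R 4.3.3 (tables were read with data.table version 1.17.8, figures drawn with Python 3.11.15 and matplotlib 3.10.9). A linear model with the 3 regions and the animal as a fixed block was fitted to all 9 arrays, so that regions shared 1 estimate of the spread, and moderated with eBayes (prior degrees of freedom 0.749). The tests were intermediate minus dorsal, intermediate minus ventral, dorsal minus ventral, intermediate minus the mean of the others, and a moderated F test over regions. P-values were adjusted by Benjamini-Hochberg over the 13959 genes and called at 0.05. Genes higher or lower in the intermediate region than in both others were those called with that sign in both pairwise tests. Values after ± are standard errors of the model unless marked SD, differences are on the log2 scale, each region has n = 3, and adjusted p-values of genes come from limma and are two-sided.

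The block rests on the titles, which name the animal of each array. Deviations of same-animal arrays from their region means correlated across genes at -0.066 to 0.246 (mean 0.081, 9 pairs, 3 of them above 0.1), and those of arrays from different animals at -0.18 to 0.161 (mean -0.041, 18 pairs).

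Before the data were examined, 26 gene lists were fixed: dystonia-associated genes, the torsin family and torsinA partners, GABAergic, glycinergic and glutamatergic neuron genes, adhesion genes of presynaptic inhibitory contacts, dorsal horn peptide and receptor genes, dorsal and ventral interneuron transcription factors, motor neuron, astrocyte, oligodendrocyte lineage, microglia, endothelial and mural, erythroid, meningeal and fibroblast, ependymal, sensory ganglion and Schwann cell genes, cell cycle genes, Hox genes, immediate early and stress genes, GABA-A receptor subunits, ionotropic glutamate receptors, voltage-gated potassium channels and axon guidance genes. Lists share members; Mbp and Sox10, for example, are on both the oligodendrocyte and the Schwann cell list, and Prph on both the motor neuron and the sensory ganglion list. Lists with at least 3 measured members were tested with camera of limma at its preset correlation between genes of 0.01, adjusted over the lists within a contrast; 75 tests resulted. Of these, 43 passed with the preset correlation, 0 passed with a correlation estimated from the data (14 at an unadjusted p under 0.05), which leaves the test only the residual degrees of freedom of the fit, and 66 passed with fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Counts of called list members are given over all genes tested and also adjusted over the list alone. Membership of a list among genes higher or lower than in both other regions was tested with Fisher's exact test against the other genes tested. Its p-values were adjusted over 26 lists and both directions, and the test was chosen after the data were seen. It treats genes as independent, whereas genes of 1 list may move together, so its p-values do not measure the spread between animals. The study followed Klhl14 and Tor1a in these samples, so the dystonia and torsin lists were chosen partly on the data they are tested on and are not independent evidence of a direction.

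Genes were named by a rule fixed at the same time. Per pairwise contrast it takes the 6 called genes with the largest log2 difference in each direction that moved the same way in all 3 animals; for the intermediate region against both others it takes 10 higher and 6 lower genes, ranked by the smaller of the differences. Numbered gene models are passed over. Any member of the dystonia and torsin lists may be named, Tor1a and Klhl14 always. Of each other list, up to 4 members that pass (the largest differences first) and up to 2 that do not (the lowest p first) may be named. Any other gene is said to have been chosen after its values were seen.

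The code was tested on simulated data for the contrast of intermediate and dorsal, with 13959 genes of which 200 were changed by known amounts. It called 50% of genes changed by a log2 difference of 0.5, 88% at 1, 96% at 2 and 68% at -1 (50 genes each), with 11 calls among unchanged genes.

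The alternatives fixed beforehand were the fit without the block or with the animal as a random block, quantile normalisation, centring of each array on its median, no filter or a filter at the 50th percentile (3.722), the mean of all probe sets or the most variable probe set of a gene, an intensity trend with a robust prior, array weights, a log2 difference of at least 1, a fit on the arrays of the regions compared, and leaving out each animal and each array. Alternatives with other pseudocounts were not run because the values were not linear. Those chosen after seeing the data were genes with 9 distinct values, a mean of at least 6, and the exclusion of the meningeal and Schwann cell lists.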

Results

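Gene expression was measured on 9 Affymetrix arrays from the spinal cords of 3 mice at postnatal day 6, with a dorsal, an intermediate and a ventral piece from each animal (n = 3 per region). The series concerns dystonia-associated genes in the circuitry of spinal GABAergic interneurons, the inhibitory neurons that use the transmitter GABA, and the design sets the 3 regions side by side. Values were read as log2 expression, and 36.0% to 36.3% of the probe sets of each array stood at the floor of 2.15. Array medians lay between 3.66 and 3.75.

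The regions separated clearly. Arrays of the same region correlated across probe sets at 0.998 to 0.9993, dorsal with intermediate at 0.9919 to 0.9952, intermediate with ventral at 0.9891 to 0.9905, and dorsal with ventral at 0.9821 to 0.9857 (genes are not independent replicates), and 0 pairs of arrays were identical. The leading principal component held 69.9% of the variance and ran from the dorsal arrays through the intermediate to the ventral ones, and the next, with 22.2%, set the intermediate arrays apart from both others. Xist, the transcript of the inactive X chromosome in females, lay between 13.2 and 14.0 on all 9 arrays, whereas the Y-linked genes Eif2s3y and Kdm5d were at the floor on all of them, Uty was at most 2.16, and Tsix, which is antisense to Xist, was at the floor too. These genes therefore gave no means of telling the animals apart. Of 13959 genes tested with limma, 8101 (58.0%) differed between any regions, and 5046 without animal 3.

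Genes that stood highest in the intermediate region included Klhl14, which encodes a kelch-like protein that binds torsinA, the ATPase encoded by the dystonia gene Tor1a. Klhl14 stood at 9.27 ± 0.18 (SD, n = 3) in intermediate pieces, against 6.22 ± 0.16 (SD) in dorsal and 5.85 ± 0.15 (SD) in ventral pieces, which was 8.22-fold (adjusted p = 0.000217) and 10.7-fold (adjusted p = 0.00012) higher. Tor1a itself lay at 8.68 in intermediate, 8.64 in dorsal and 8.59 in ventral pieces, with differences of 0.04 ± 0.05 (adjusted p = 0.607) and 0.10 ± 0.05 (adjusted p = 0.168) that did not pass the test. Tfap2b, a transcription factor of the AP-2 family, was 20.8-fold higher in intermediate than in dorsal pieces and 140-fold higher than in ventral ones. Lhx9, a LIM homeobox transcription factor, reached 6.05 ± 0.40 (SD) in intermediate pieces and was at the floor on every dorsal and ventral array, at least 15.01-fold lower.

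Among the other genes with the largest excess over both regions were Amn (2.75 ± 0.17 over dorsal and 3.36 over ventral), Tfap2a (2.19 ± 0.24 and 2.91), Ctxn3 (2.20 ± 0.24 and 2.04), Cartpt, the precursor of the CART peptide (2.45 ± 0.17 and 1.93), the contactin Cntn5 (1.92 ± 0.16 and 2.09), Neurod1 (1.80 ± 0.21 and 2.72) and the cadherin Cdh7 (2.10 ± 0.13 and 1.73), all with adjusted p of at most 0.00422. The 3 dorsal values of Cartpt were identical, so that its spread there was not measured. With 1 animal left out, the calls over dorsal of Tfap2a (adjusted p = 0.0639 without animal 2), Ctxn3 (adjusted p = 0.0685 without animal 2), Cntn5 (adjusted p = 0.0516 without animal 3) and Neurod1 (adjusted p = 0.0678 without animal 1) were lost, as was that of Ctxn3 over ventral (adjusted p = 0.0532 without animal 2). A dimmer probe set of Cdh7 gave -0.06 against dorsal.

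Genes lowest in the intermediate region included Pmp2, a lipid-binding protein of peripheral myelin, which lay near the floor at 2.45 ± 0.43 (SD) there, so that its differences are lower bounds of the fall, 8.65 ± 1.47 (SD) in dorsal and 9.97 ± 0.38 (SD) in ventral pieces. Others were the proteoglycan genes Ogn (-5.22 ± 0.54 against dorsal and -5.26 against ventral) and Dcn (-3.99 ± 0.42 and -4.40), the peripheral myelin gene Pmp22 (-4.09 ± 0.40 and -3.96), the collagen gene Col1a1 (-3.41 ± 0.47 and -4.47) and Smco3 (-3.28 ± 0.61 and -3.64), with adjusted p from 0.00115 to 0.0176. Without animal 3, the calls against dorsal were lost for Pmp2 (adjusted p = 0.0589), Ogn (0.0709), Dcn (0.0826), Pmp22 (0.0607), Col1a1 (0.12) and Smco3 (0.117), and that of Smco3 against ventral as well (adjusted p = 0.0695).

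By group, 5 of 8 measured glycinergic genes were higher in the intermediate region than in both others, namely the glycine transporter Slc6a5, the vesicular transporter Slc32a1 and the receptor genes Glra1, Glra2 and Glrb (Fisher's exact test adjusted over 26 lists and both directions, adjusted p = 0.000588). The same count was found among adhesion genes of presynaptic inhibitory contacts (Cntn1, Cntn4, Cntn5, Cntnap2 and Cntnap4; 5 of 8, adjusted p = 0.000588). Of 10 GABAergic genes, 4 were higher than in both: Gad2, Slc32a1, Abat and Nrxn3 (adjusted p = 0.0245). Ionotropic glutamate receptors (4 of 14, adjusted p = 0.0795) and Hox genes (5 of 25, adjusted p = 0.131) did not pass. Lower than in both were 9 of 15 microglia genes, C1qa, C1qb, C1qc, P2ry12, Csf1r, Cx3cr1, Ctss, Tyrobp and Aif1, and 9 of 15 meningeal and fibroblast genes, Col1a1, Col1a2, Col3a1, Dcn, Ogn, Fmod, Igf2, Foxc1 and Aldh1a2 (adjusted p = 3.96e-08 for each list). Every other list had an adjusted p of at least 0.19 in both directions. Fisher's test treats genes as independent, and its p-values do not measure the spread between animals. The correlation between genes estimated by camera was 0.233 for the microglia, 0.486 for the meningeal and 0.442 for the adhesion list. It was 0.228 for the glycinergic and 0.008 for the GABAergic list. Some genes of these sets lie outside the rule for named genes and were chosen after their values were seen. These groupings depended on which animal was left out, with fewer calls in either pairwise test when any 1 was missing. Without animal 2, the glycinergic and adhesion lists (4 of 8, adjusted p = 0.00387 for both) still passed. So did the meningeal (8 of 15, adjusted p = 1.15e-08) and microglia lists (5 of 15, adjusted p = 0.000281). Without animal 3 the members fell to 0 for the adhesion, meningeal and microglia lists and to 1 for the GABAergic list (adjusted p = 1 for each). Without animal 1 they fell to 2 for the glycinergic and the adhesion list (adjusted p = 0.185 for both), to 1 for the GABAergic and to 0 for the microglia list (adjusted p = 1 for both). The GABAergic grouping was also lost without animal 2 (3 of 10, adjusted p = 0.0731), without the animal block (3 of 10, adjusted p = 0.14), with the filter at the 50th percentile (0.148), with a mean of at least 6 (0.137) and with genes of 9 distinct values (0.233). Single arrays mattered too: the GABAergic grouping was lost without dorsal array 1 (0.0874), intermediate 3 (0.0522), ventral 2 (0.0679) or ventral 3 (0.0724). The adhesion grouping was lost without dorsal 1 (0.228), dorsal 3 (0.194), intermediate 1 (0.185), intermediate 2 (0.0975), intermediate 3 (0.216) or ventral 3 (0.268), and the microglia grouping without dorsal 3 (0.0534) or intermediate 3 (0.0677). Of 25 alternatives in all, the grouping passed in 24 for the glycinergic list, 21 for the microglia, 15 for the adhesion and 14 for the GABAergic list, and for the meningeal list in 23 of the 24 that keep its genes. Other probe sets of Cntn1 gave -1.50 against ventral and of Cntnap2 -0.18 against dorsal, and the adhesion grouping did not pass with the most variable probe set of each gene (3 genes, adjusted p = 0.0621) or without the filter on dim probe sets (2 genes, adjusted p = 0.211).

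In all, 873 genes were higher and 586 lower in the intermediate region than in both others. Lists of these sizes that were independent would share 518 and 493 genes. Genes called with opposite signs also exceeded independence, with 715 higher than dorsal and lower than ventral against 552, and 803 lower than dorsal and higher than ventral against 463. With each array centred on its median, 1230 genes were higher and 430 lower than in both. The differences from dorsal and from ventral correlated across genes at 0.05 (0.498 in the simulations without effects) with a covariance of 0.0152 (0.0064 simulated). The simulations gave all regions the same mean, so these values do not show how much sharing adds where regions differ. At most 0 genes were called higher or lower than both in any of the 50 simulations. Both comparisons use the same 3 intermediate arrays, which are too few to split, so part of the overlap may come from sharing them. Against the mean of the other regions, 2625 genes were higher and 2502 lower. The counts fell when an animal was left out, and by how much depended on the animal. Without animal 3, 235 genes were higher than both, 175 lower than both, and 1477 differed from the mean of the others. Without animal 1 these counts were 365, 211 and 2074, and without animal 2 they were 660, 298 and 3340. Without intermediate array 1 they were 508, 347 and 2919, without intermediate array 3, 553 were higher and 3396 differed from the mean, and without dorsal array 3, 381 were lower.

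**Figure D1:**
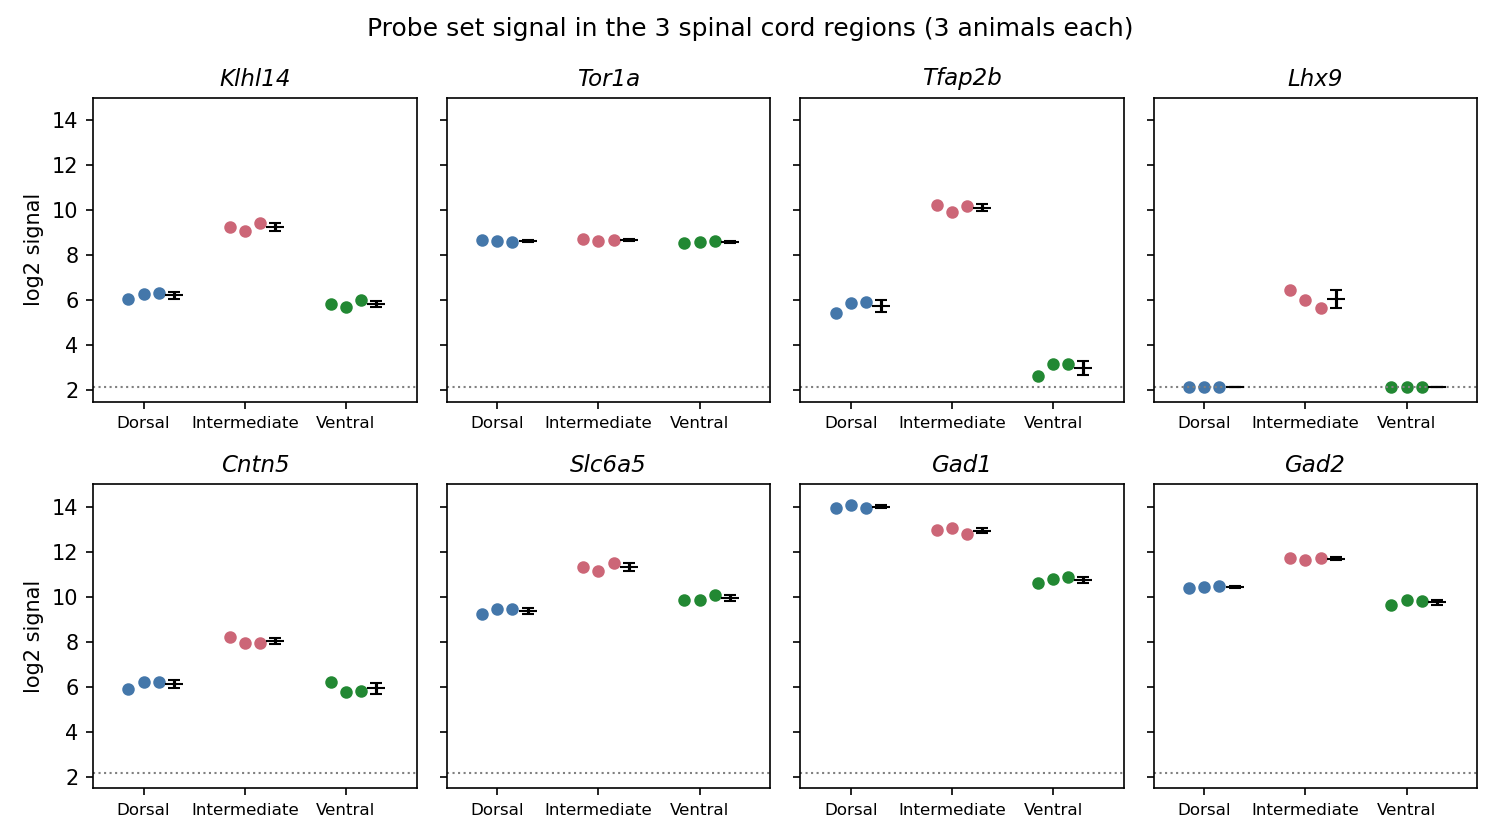
Log2 expression (vertical axis) of Klhl14, Tor1a, Tfap2b, Lhx9, Cntn5, Slc6a5, Gad1 and Gad2 in dorsal, intermediate and ventral pieces; points are the 3 animals, black bars the mean ± SD, and the dotted line the floor of 2.15. Klhl14 averaged 9.27 in intermediate pieces against 6.22 and 5.85, Tor1a lay between 8.59 and 8.68 in all regions, and Gad1 fell from 14.0 in dorsal to 10.7 in ventral pieces.

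**Figure D2:**
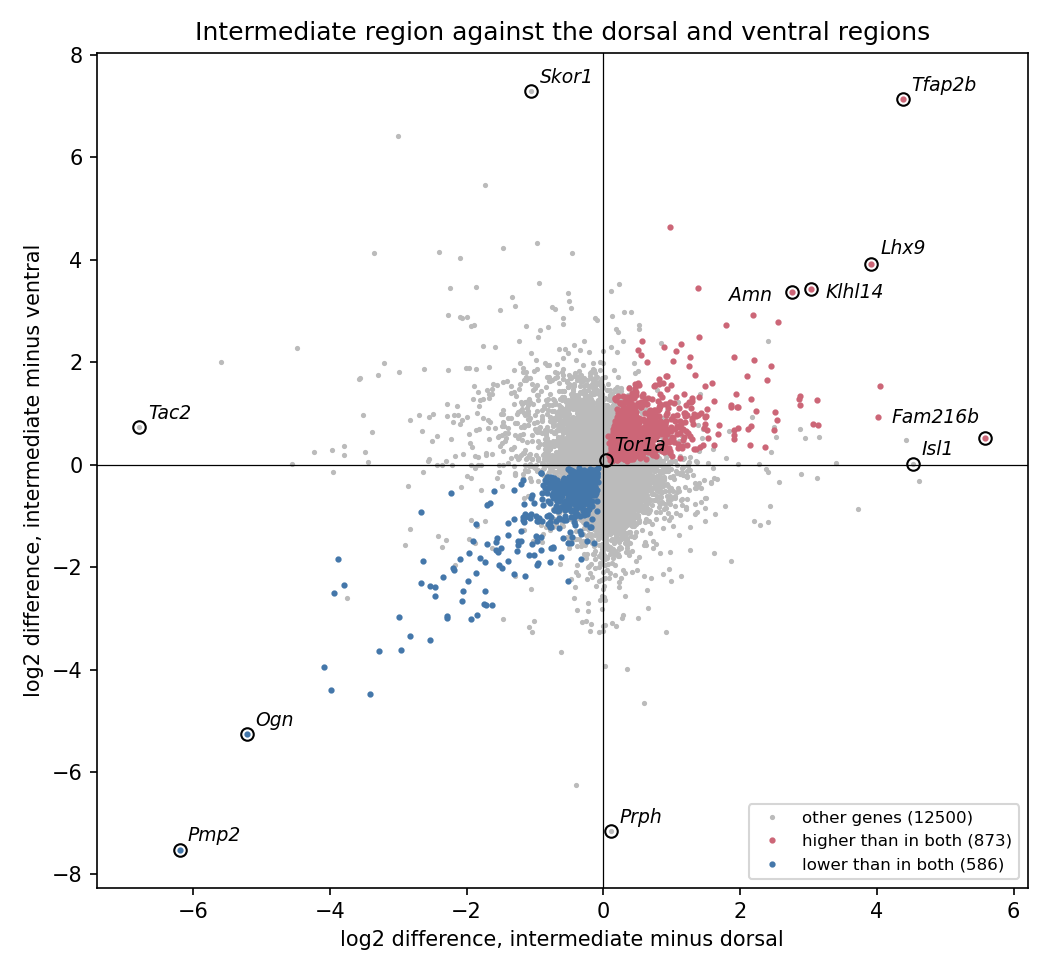
Log2 difference of intermediate from dorsal (horizontal axis) against that of intermediate from ventral (vertical axis) for 13959 genes; red points are the 873 genes higher than in both regions, blue points the 586 lower than in both, and grey points the other 12500. Klhl14 lies at 3.04 and 3.42, and Pmp2 at -6.20 and -7.52.

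Of the dystonia-associated genes, 22 were measured, and those other than Klhl14 followed no common direction. In intermediate against dorsal pieces, 5 were higher (Klhl14, Pnkd by 1.25 ± 0.04, the glucose transporter Slc2a1 by 0.78 ± 0.07, Spr by 0.50 ± 0.12 and Tubb4a by 0.29 ± 0.07) and 4 lower (Col6a3 by -1.85 ± 0.41, the calcium channel Cacna1b by -0.43 ± 0.06, the adenylyl cyclase Adcy5 by -0.41 ± 0.05 and Kmt2b by -0.22 ± 0.06). Against ventral pieces 8 were higher, led by Klhl14, Hpca (1.71 ± 0.10), Cacna1b (1.35 ± 0.06) and Adcy5 (0.86 ± 0.05), and 4 lower, led by Col6a3 (-2.94 ± 0.41) and Tubb4a (-1.04 ± 0.07). Between dorsal and ventral pieces, 10 were higher in dorsal and 5 in ventral; Hpca (1.81 ± 0.10) and Slc2a1 (-1.28 ± 0.07) are examples, and Klhl14 differed by 0.38 ± 0.09 (adjusted p = 0.0212, but 0.152 without animal 3). Counts adjusted over the list alone were identical. Because the study followed Klhl14 and Tor1a in these samples, the list is not independent evidence of a direction. As a whole the list was not shifted against other genes by camera (adjusted p = 0.941, 0.132 and 0.389 in the order given). Between intermediate and dorsal pieces its median (-0.02) and its mean (0.11) differed in sign. With 1 animal left out, the calls against dorsal of 7 of these 9 genes were lost, at adjusted p between 0.0564 for Slc2a1 and 0.308 for Kmt2b, both without animal 3; those of Klhl14 and Pnkd were not. That of Tubb4a was also lost without the animal block (adjusted p = 0.14). Against ventral, the calls of 5 of the 12 genes were lost, Gnal (0.0669 without animal 2), Kcnma1 (0.201 without animal 1), Kmt2b (0.174 without animal 2), Prkra (0.0685 without animal 3) and Slc2a1 (0.0716 without animal 3). Between dorsal and ventral, 7 of 15 were lost, at adjusted p from 0.0508 for Kmt2b to 0.204 for Taf1, both without animal 2. Other probe sets turned the direction of Sgce against ventral (0.313) and between dorsal and ventral (0.667), and of Kcnma1 between dorsal and ventral (-0.523).

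Of 13 measured genes of the torsin family and torsinA partners, 3 were higher in intermediate than in dorsal pieces: Klhl14, the nesprin Syne1 (0.49 ± 0.08) and Tor1aip1, which encodes a torsin-binding protein of the inner nuclear membrane (0.23 ± 0.06). The nuclear envelope genes Syne2 (-0.54 ± 0.07) and Sun1 (-0.36 ± 0.07) were lower. Against ventral pieces Klhl14, Syne1 (0.50 ± 0.08) and Syne2 (0.33 ± 0.07) were higher, and 6 genes were lower, among them Tor1aip2 (-0.72 ± 0.06), Kif5b (-0.65 ± 0.17), Snapin (-0.61 ± 0.05) and Tor1b (-0.34 ± 0.06). In dorsal against ventral pieces 3 were higher and 4 lower, Tor1aip2 by -0.92 ± 0.06. Adjusted over the list alone, 5 were higher and 3 lower than in dorsal pieces, with identical counts elsewhere, and this list too was chosen partly on these samples and is not independent evidence. Camera found no shift (adjusted p = 0.582, 0.57 and 0.523 in the same order), and against ventral the median (-0.24) and the mean (0.08) differed in sign. With 1 animal left out, the calls against dorsal were lost for Tor1aip1 (adjusted p = 0.275 without animal 1), Syne1 (0.106 without animal 3), Syne2 (0.0883 without animal 2) and Sun1 (0.164 without animal 2). Those of Tor1aip1 (adjusted p = 0.101) and Sun1 (0.0573) were also lost without the animal block. Against ventral they were lost for 6 of 9 genes, Syne1 (0.0792 without animal 3), Syne2 (0.104 without animal 2), Kif5b (0.225 without animal 3), Tor1b (0.124 without animal 1), Sun2 (0.151 without animal 2) and Tor1aip1 (0.0641 without animal 1). Between dorsal and ventral they were lost for Klhl14 (without animal 3, as given above), Kif5b (0.155 without animal 3) and Sun1 (0.0555 without animal 2). Another probe set turned the direction for Syne1 against dorsal (-0.03), for Syne2 (-0.02) and Snapin (0.04) against ventral, and for Kif5b between dorsal and ventral (0.292).

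Intermediate pieces were set against dorsal pieces to find what distinguishes these neighbouring regions. The largest excess was that of Fam216b (5.59 ± 0.14, or 48.0-fold), followed by Tm4sf1 (4.62 ± 0.06), the LIM homeobox gene Isl1 (at least 23.0-fold, near the floor in dorsal pieces), the dynein light chain gene Dynlrb2 (21.5-fold), Tfap2b (4.38 ± 0.17) and Crabp1, which binds retinoic acid (4.05 ± 0.08), with adjusted p of at most 0.000611. Tac2, the neurokinin B precursor, was at least 110-fold lower, with 2 of 3 intermediate arrays at the floor and 4.35 on that of animal 2, and Pmp2 was at least 73.4-fold lower, near the floor in intermediate pieces. The transcription factor gene Ebf2 (-5.59 ± 0.39), Ogn (-5.22 ± 0.54), the immediate early gene Egr3 (at least 23.5-fold lower, near the floor in intermediate pieces) and the homeobox gene Prrxl1 (22.2-fold lower) followed, with adjusted p of at most 0.00324. The call of Egr3 was lost without animal 2 (adjusted p = 0.0527).

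In total, 2219 genes were higher and 1983 lower in intermediate than in dorsal pieces, 30.1% of those tested, and 537 differed at least by a factor of 2. Centring each array on its median moved the split to 3222 higher and 1540 lower. The count fell to 1464 without animal 3, 1903 without animal 1 and 2454 without animal 2, and was 2105 when only the arrays of these regions entered the fit.

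Neuronal groups moved in different directions between these regions. Of 8 glycinergic genes, 6 were higher and 0 lower in intermediate pieces, Slc6a5 by 1.94 ± 0.08, Slc6a9 by 0.98 ± 0.07 and the glycine receptor gene Glra1 by 0.97 ± 0.06. The median difference was 0.71 (camera adjusted p = 0.00017, adjusted p = 0.311 with an estimated correlation). The 10 GABAergic genes split evenly, 5 higher and 5 lower: Gad2, which encodes GAD65, was higher by 1.26 ± 0.06, whereas the transcription factor genes Gbx1 (-3.52 ± 0.22), Lhx1 (-1.28 ± 0.09) and Sall3 (-1.15 ± 0.22) were lower, as was Gad1, which encodes GAD67, by -1.06 ± 0.09 (camera adjusted p = 0.82). Gad1 was chosen for this comparison after its values were seen. Glutamatergic genes were lower in 5 of 6 cases and higher in 0, Lmx1b by -3.56 ± 0.21, Ebf1 by -3.21 ± 0.25 and Ebf3 by -2.10 ± 0.09, while the vesicular glutamate transporter gene Slc17a6 differed by -0.02 ± 0.06. Their median was -2.65 (camera adjusted p = 0.000728, adjusted p = 0.311 with an estimated correlation). Dorsal horn peptide and receptor genes were lower in 20 and higher in 2 of 27 cases, Cck by -3.00 ± 0.15 and Sst by -2.51 ± 0.15, against Cartpt higher by 2.45 ± 0.17. The list had a median of -1.24 (camera adjusted p = 2.4e-08, adjusted p = 0.311 with an estimated correlation). Adhesion genes of inhibitory contacts were higher in 6 of 8 cases and lower in 1, Chl1 by -0.36 ± 0.04 (adjusted over the list alone 6 and 2; camera adjusted p = 0.161). Another probe set of Chl1 gave 0.05. Without animal 3 the calls of Sall3 (adjusted p = 0.184) and Slc32a1 (0.0912) were lost, among others, such as that of the adhesion gene Cntn5 given above.

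Transcription factors of ventral interneurons were higher in 7 of 22 cases and lower in 0, Foxp2 by 3.73 ± 0.21, Nr4a2 by 2.28 ± 0.30 and Shox2 by 2.17 ± 0.47 (median 0.21, camera adjusted p = 0.0053, and adjusted p = 0.311 with an estimated correlation); without animal 3 the calls of Nr4a2 (adjusted p = 0.1) and Shox2 (0.151) were lost. Those of dorsal interneurons split into 5 higher and 10 lower of 23 (camera adjusted p = 0.321), or 8 and 11 adjusted over the list alone. Motor neuron genes were higher in 8 of 25 cases, with Isl1, Esrrg (2.89 ± 0.09) and Nefh (2.20 ± 0.14) in the lead, and lower in 1 (median 0.11, camera adjusted p = 0.0495, but adjusted p = 0.666 with an estimated correlation), and this shift was also lost with quantile normalisation and with the mean of all probe sets. Hox genes gave 6 higher and 10 lower of 25 (7 and 11 adjusted over the list alone; camera adjusted p = 0.571), with Hoxd10 (2.52 ± 0.07) and Hoxc10 (2.23 ± 0.09) higher and Hoxb6 (-1.67 ± 0.05) lower.

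Ependymal genes, which serve the ciliated lining of the central canal, were higher in intermediate than in dorsal pieces in 10 of 12 cases and lower in 0, Enkur by 3.14 ± 0.17 and Foxj1 by 2.16 ± 0.11 (11 adjusted over the list alone). Across the list the median was 1.05 (camera adjusted p = 6.3e-06, adjusted p = 0.311 with an estimated correlation). Astrocyte genes were higher in 10 of 16 cases, such as the glutamate transporter gene Slc1a3 (0.99 ± 0.07) and Fgfr3 (0.69 ± 0.04), and lower in 1, Gfap by -1.63 ± 0.16 (median 0.34, camera adjusted p = 0.000728, and adjusted p = 0.424 with an estimated correlation); the call of Gfap was lost without animal 3 (adjusted p = 0.0582). Microglia genes were lower in 9 of 15 cases (10 adjusted over the list alone) and higher in 0, C1qa by -0.69 ± 0.12 and P2ry12 by -0.96 ± 0.22. These genes had a median of -0.37 (camera adjusted p = 0.000886, adjusted p = 0.424 with an estimated correlation). These calls were among the least stable, with adjusted p = 0.0955 for C1qa without animal 2 and 0.262 for P2ry12 without animal 3, and all 9 were lost in some fit with 1 animal left out. Against ventral pieces 6 of these 9 were lost, C1qc (0.195 without animal 2), P2ry12 (0.136 without animal 3), C1qb (0.113 without animal 1), Aif1 (0.0755 without animal 3), Cx3cr1 (0.0624 without animal 3) and C1qa (0.0599 without animal 2). Meningeal and fibroblast genes were lower in 10 of 15 cases (12 adjusted over the list alone) and higher in 0, Col3a1 by -2.99 ± 0.34. In the median they differed by -1.63 (camera adjusted p = 5.95e-05, adjusted p = 0.447 with an estimated correlation). Schwann cell genes were lower in 4 of 8, Pmp22, Egr2 (-3.94 ± 0.70), Ncmap (-3.74 ± 0.81) and Drp2 (-0.62 ± 0.08), and higher in 0. All tested members together had a median of -0.41 (camera adjusted p = 0.0344, adjusted p = 0.605 with an estimated correlation). Egr2 (adjusted p = 0.135) and Ncmap (0.18) were lost without animal 2, and Col3a1 (0.0887) and Drp2 (0.101) without animal 3. The mean of the meningeal genes was 8.49, 7.38 and 8.13 on the dorsal arrays, 5.77, 6.03 and 6.20 on the intermediate and 8.47, 8.48 and 8.11 on the ventral ones.

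The remaining lists showed no shift between intermediate and dorsal pieces with camera, at adjusted p from 0.164 to 0.746. Oligodendrocyte lineage genes were higher in 5 of 20 cases, Olig1 by 0.48 ± 0.04 and Cspg4 by 0.42 ± 0.02. Endothelial and mural genes were higher in 3 of 16 (1 adjusted over the list alone), and cell cycle genes in 1 of 23 (0 adjusted over the list alone). Immediate early and stress genes were higher in 3 and lower in 7 of 24, Egr1 by -2.09 ± 0.25 (lost without animal 1, adjusted p = 0.0762). Ionotropic glutamate receptors were higher in 4 and lower in 6 of 14 (4 and 7 adjusted over the list alone), Gria2 by -1.19 ± 0.07. Potassium channel genes were higher in 5 and lower in 8 of 20 (6 and 8 adjusted over the list alone), Kcnc2 by -1.86 ± 0.07. GABA-A receptor subunits were higher in 3 and lower in 2 of 9 (3 and 3 adjusted over the list alone), Gabrb1 by 0.52 ± 0.03. Axon guidance genes were higher in 13 and lower in 9 of 40 (14 and 10 adjusted over the list alone), Sema3a by 2.41 ± 0.14 and Epha4 by 1.91 ± 0.08. Sensory ganglion genes were lower in 3 of 8, Gal, Pou4f1 and Tac1 (the call of Pou4f1 was lost without animal 3, adjusted p = 0.288). Both measured erythroid genes, Alas2 (-0.01 ± 0.01) and Slc4a1 (0.01 ± 0.24), were below the number needed for a test and passed in 0 of the 3 contrasts. Counts adjusted over the list alone were identical wherever none is given.

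Intermediate and ventral pieces differed more widely. The transcriptional corepressor gene Skor1 was 157-fold higher in intermediate pieces (7.29 ± 0.12), Tfap2b 140-fold, and the protease inhibitor gene Serpinb1b 85.4-fold (6.42 ± 0.25), ahead of Ipcef1 (5.45 ± 0.24), Neurod6 (4.65 ± 0.09) and Bcl11b (4.33 ± 0.32). Lower were Pmp2 (-7.52 ± 0.64) and Prph, which encodes the neuronal intermediate filament peripherin (at least 142-fold), both near the floor in intermediate pieces, Fads2b (-6.25 ± 0.21), Ogn (-5.26 ± 0.54), Calcb, the precursor of a calcitonin gene-related peptide (-4.66 ± 0.18), and Col1a1 (-4.47 ± 0.47). All 12 had adjusted p of at most 0.00153. Of the genes tested, 3260 were higher and 3471 lower, 48.2% together, and 1328 differed at least by a factor of 2. Without animal 3 the count was 4200.

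Genes of every neuronal transmitter list were mostly higher in intermediate than in ventral pieces. GABAergic genes were higher in 8 of 10 cases and lower in 0, Gad1 by 2.19 ± 0.09 and Gad2 by 1.93 ± 0.06. The median difference was 1.03 (camera adjusted p = 0.000284, adjusted p = 0.214 with an estimated correlation). Glycinergic genes were higher in 7 of 8 and lower in 1, Slc32a1 by 1.55 ± 0.09, Glra3 by 1.46 ± 0.05 and Slc6a5 by 1.38 ± 0.08. Their median was 0.65 (camera adjusted p = 0.00147, adjusted p = 0.214 with an estimated correlation). Glutamatergic genes were higher in 5 of 6 and lower in 0, Ebf3 by 4.04 ± 0.09. The list had a median of 1.83 (camera adjusted p = 0.00337, adjusted p = 0.214 with an estimated correlation). Adhesion genes of inhibitory contacts were higher in 7 of 8 and lower in 0, Cntnap4 by 1.59 ± 0.11 and L1cam by 1.34 ± 0.07. Across the list the median was 1.27 (camera adjusted p = 0.000119, adjusted p = 0.214 with an estimated correlation). Dorsal horn peptide and receptor genes were higher in 18 of 27 (19 adjusted over the list alone) and lower in 0, Grp by 4.15 ± 0.24, Tac1 by 3.07 ± 0.06 and Npy by 2.89 ± 0.05. These genes had a median of 1.03 (camera adjusted p = 1.33e-07, adjusted p = 0.214 with an estimated correlation). Ionotropic glutamate receptors were higher in 13 of 14 and lower in 0, Grik1 by 1.60 ± 0.02 (median 0.76, camera adjusted p = 3.75e-06, and adjusted p = 0.157 with an estimated correlation), and potassium channel genes higher in 14 of 20 and lower in 1, Kcnip2 by 2.31 ± 0.07. In the median they differed by 0.68 (camera adjusted p = 2.81e-05, adjusted p = 0.214 with an estimated correlation). GABA-A receptor subunits were higher in 4 and lower in 4 of 9 (camera adjusted p = 0.625), Gabra3 by 1.32 ± 0.05.

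Dorsal interneuron transcription factors were higher in intermediate than in ventral pieces in 16 of 23 cases (17 adjusted over the list alone) and lower in 1, Pou4f1 by 3.54 ± 0.23 and Bcl11a by 3.34 ± 0.09. All tested members together had a median of 1.26 (camera adjusted p = 1.53e-05, adjusted p = 0.214 with an estimated correlation). Hox genes were higher in 15 of 25 (16 adjusted over the list alone) and lower in 2, Hoxb9 by 3.28 ± 0.11 against Hoxd1 lower at least 3.54-fold, near the floor in intermediate pieces. The median difference was 0.60 (camera adjusted p = 0.000209, adjusted p = 0.214 with an estimated correlation). Motor neuron genes were lower in 12 of 25 (13 adjusted over the list alone) and higher in 2, Hspb8 by -3.65 ± 0.21 beside Prph and Calcb. Their median was -0.48 (camera adjusted p = 0.000567, adjusted p = 0.307 with an estimated correlation). Ventral interneuron transcription factors were higher in 2 and lower in 7 of 22 (2 and 6 adjusted over the list alone; camera adjusted p = 0.24), Nkx6-1 at least 6.02-fold, since it was at the floor in intermediate pieces. Axon guidance genes were higher in 14 and lower in 11 of 40 (camera adjusted p = 0.227), Sema3d by -1.44 ± 0.08 and Efna5 by 1.40 ± 0.04. Immediate early and stress genes were higher in 5 and lower in 5 of 24 (camera adjusted p = 0.997), and sensory ganglion genes higher in 3 and lower in 2 of 8 (camera adjusted p = 0.57, with a median of 0.01 and a mean of -0.08).

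Most genes of the oligodendrocyte, astrocyte, microglia, endothelial, meningeal and cell cycle lists were lower in intermediate than in ventral pieces. Oligodendrocyte lineage genes were lower in 19 of 20 cases and higher in 0, the myelin genes Mal by -3.17 ± 0.40, Ermn by -3.06 ± 0.12 and Mog by -2.99 ± 0.21, whereas Mbp, which encodes myelin basic protein, lay at 15.94 and 15.97 and differed by -0.04 ± 0.02; its values were close to the highest on each array (16.11 to 16.27), where a saturated signal would hide a difference. The list had a median of -1.31 (camera adjusted p = 4.39e-08, adjusted p = 0.214 with an estimated correlation). Cell cycle genes were lower in 20 of 23 (21 adjusted over the list alone) and higher in 0, the mitotic kinase gene Bub1 by -1.43 ± 0.05. Across the list the median was -0.86 (camera adjusted p = 1.34e-06, adjusted p = 0.214 with an estimated correlation). Astrocyte genes were lower in 12 of 16, Gfap by -2.74 ± 0.16. These genes had a median of -0.49 (camera adjusted p = 0.000237, adjusted p = 0.224 with an estimated correlation). Endothelial and mural genes were lower in 13 of 16, Acta2 by -2.13 ± 0.13. In the median they differed by -0.61 (camera adjusted p = 0.000108, adjusted p = 0.214 with an estimated correlation). Microglia genes were lower in 11 of 15, Tyrobp by -0.83 ± 0.11. All tested members together had a median of -0.53 (camera adjusted p = 0.0011, adjusted p = 0.27 with an estimated correlation). Meningeal and fibroblast genes were lower in 11 of 15, Lum by -3.05 ± 0.34. The median difference was -2.20 (camera adjusted p = 0.000209, adjusted p = 0.304 with an estimated correlation). Schwann cell genes were lower in 3 of 8, Pmp22, Egr2 and Sox10. Their median was -1.14 (camera adjusted p = 0.0397, adjusted p = 0.413 with an estimated correlation). In each of these lists 0 genes were higher. Ependymal genes were higher in 3 of 12 and lower in 0, Enkur by 0.78 ± 0.17, Foxj1 by 0.75 ± 0.11 and Cfap126 by 0.35 ± 0.08 (median 0.50, camera adjusted p = 0.023, and adjusted p = 0.3 with an estimated correlation), and each of these 3 calls was lost with an animal left out (adjusted p = 0.109, 0.0799 and 0.126). The call of Egr2 was lost without animal 2 (adjusted p = 0.223).

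Dorsal and ventral pieces, the ends of the axis, differed in most genes. Serpinb1b was 682-fold higher in dorsal pieces (9.41 ± 0.25) and Skor1 327-fold (8.35 ± 0.12), followed by Ebf2 (at least 193-fold, near the floor in ventral pieces), Tac2 (at least 184-fold, since it was at the floor in ventral pieces), Ipcef1 (7.19 ± 0.24) and Prrxl1 (6.75 ± 0.33). Prph was at the floor in dorsal pieces, at least 154-fold lower than in ventral ones, and Fads2b (-5.84 ± 0.21, with 3 identical dorsal values), Calcb (38.2-fold lower), Fam216b (-5.07 ± 0.14), Tm4sf1 (-4.93 ± 0.06) and the forkhead gene Foxp2 (-4.59 ± 0.21) were also lower, with adjusted p of at most 0.000321 for all 12. In total 3425 genes were higher in dorsal and 3939 in ventral pieces (52.8% of those tested), and 1802 differed at least by a factor of 2. Of these 7364 genes, the intermediate mean lay between the dorsal and ventral means for 4700 (63.8%), above both for 1367 (18.6%) and below both for 1297 (17.6%).

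Most neuronal groups were higher in dorsal than in ventral pieces. Dorsal horn peptide and receptor genes were higher in 24 of 27 cases and lower in 0 (1 adjusted over the list alone), Grp by 6.56 ± 0.24, Npy by 4.99 ± 0.05 and Cck by 4.81 ± 0.15. The list had a median of 2.36 (camera adjusted p = 1.09e-10, adjusted p = 0.156 with an estimated correlation). Glutamatergic genes were higher in 6 of 6, Ebf3 by 6.14 ± 0.09 and Lmx1b by at least 5.24 ± 0.21, near the floor in ventral pieces. Across the list the median was 5.21 (camera adjusted p = 0.000269, adjusted p = 0.156 with an estimated correlation). GABAergic genes were higher in 8 of 10 and lower in 1, Gbx1 at least 22.5-fold (at the floor in ventral pieces) and Gad1 by 3.25 ± 0.09. These genes had a median of 0.73 (camera adjusted p = 0.0025, adjusted p = 0.156 with an estimated correlation). Glycinergic genes split into 5 higher, such as Glra3 (1.37 ± 0.05), and 3 lower, such as Slc6a9 (-1.47 ± 0.07), of 8 (camera adjusted p = 0.477). Adhesion genes of inhibitory contacts were higher in 5 of 8 and lower in 0, L1cam by 1.61 ± 0.07. In the median they differed by 0.86 (camera adjusted p = 0.00876, adjusted p = 0.35 with an estimated correlation). Ionotropic glutamate receptors were higher in 10 and lower in 1 of 14, Gria2 by 2.29 ± 0.07 (median 1.08, camera adjusted p = 0.00035, and adjusted p = 0.156 with an estimated correlation), and potassium channel genes higher in 12 and lower in 2 of 20 (12 and 3 adjusted over the list alone), Kcnip2 by 4.08 ± 0.07. All tested members together had a median of 1.09 (camera adjusted p = 0.00035, adjusted p = 0.267 with an estimated correlation). GABA-A receptor subunits were higher in 4 and lower in 4 of 9 (camera adjusted p = 0.708), Gabra5 by 1.67 ± 0.07.

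Dorsal interneuron transcription factors were higher in dorsal pieces in 18 of 23 cases and lower in 3, Bcl11b by 5.30 ± 0.32 and Lbx1 by 4.88 ± 0.15. The median difference was 1.52 (camera adjusted p = 1.1e-05, adjusted p = 0.156 with an estimated correlation). Ventral interneuron transcription factors were lower in 10 of 22 and higher in 0, among them Foxp2 and Nkx6-1 (at least 6.03-fold, at the floor in dorsal pieces). Their median was -0.60 (camera adjusted p = 0.00371, adjusted p = 0.156 with an estimated correlation). Motor neuron genes were lower in 15 of 25 and higher in 2, Prph, Calcb, Isl1 (at least 22.7-fold) and Pappa (-3.76 ± 0.14) in the lead. The list had a median of -1.14 (camera adjusted p = 0.000324, adjusted p = 0.35 with an estimated correlation). Chat, the choline transporter gene Slc5a7 and the vesicular acetylcholine transporter gene Slc18a3 were not analysed here. Hox genes were higher in 13 and lower in 6 of 25, Hoxb9 by 4.61 ± 0.11 and Hoxb5 by 3.56 ± 0.23. Across the list the median was 0.58 (camera adjusted p = 0.0259, adjusted p = 0.341 with an estimated correlation). Immediate early and stress genes were higher in 9 and lower in 1 of 24 (camera adjusted p = 0.285), Egr3 at least 23.6-fold (near the floor in ventral pieces) and Npas4 by 2.34 ± 0.13. Axon guidance genes were higher in 16 and lower in 14 of 40 (camera adjusted p = 0.574), and sensory ganglion genes higher in 3 and lower in 2 of 8 (camera adjusted p = 0.523).

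Ventral pieces carried the higher oligodendrocyte, astrocyte, ependymal, vascular and cell cycle values. Oligodendrocyte lineage genes were lower in dorsal pieces in 19 of 20 cases and higher in 0, Mog by -3.26 ± 0.21 and Ermn by -2.81 ± 0.12. These genes had a median of -1.32 (camera adjusted p = 2.02e-07, adjusted p = 0.267 with an estimated correlation). Astrocyte genes were lower in 15 of 16, Slc1a3 by -1.47 ± 0.07 and S100b by -1.42 ± 0.04. In the median they differed by -0.76 (camera adjusted p = 1.1e-05, adjusted p = 0.219 with an estimated correlation). Cell cycle genes were lower in 20 of 23 (21 adjusted over the list alone), Bub1 by -1.67 ± 0.05. All tested members together had a median of -0.94 (camera adjusted p = 8.3e-06, adjusted p = 0.254 with an estimated correlation). Endothelial and mural genes were lower in 13 of 16 (14 adjusted over the list alone), Acta2 by -3.01 ± 0.13. The median difference was -0.83 (camera adjusted p = 9.76e-05, adjusted p = 0.156 with an estimated correlation). Ependymal genes were lower in 7 of 12, Dynlrb2 by -3.94 ± 0.16 and Enkur by -2.36 ± 0.17. Their median was -0.81 (camera adjusted p = 0.00605, adjusted p = 0.267 with an estimated correlation). In these 5 lists 0 genes were higher. Microglia genes differed in 1 of 15, Ctss by -0.51 ± 0.05 (camera adjusted p = 0.301), meningeal and fibroblast genes in 3 of 15 (2 adjusted over the list alone), such as Mgp by -2.45 ± 0.21 (camera adjusted p = 0.393), and Schwann cell genes in 1 each way of 8, Sox10 by -1.33 ± 0.11 and Drp2 by 0.55 ± 0.08 (camera adjusted p = 0.812). The call of Drp2 was lost without animal 3 (adjusted p = 0.0627).

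**Figure D3:**
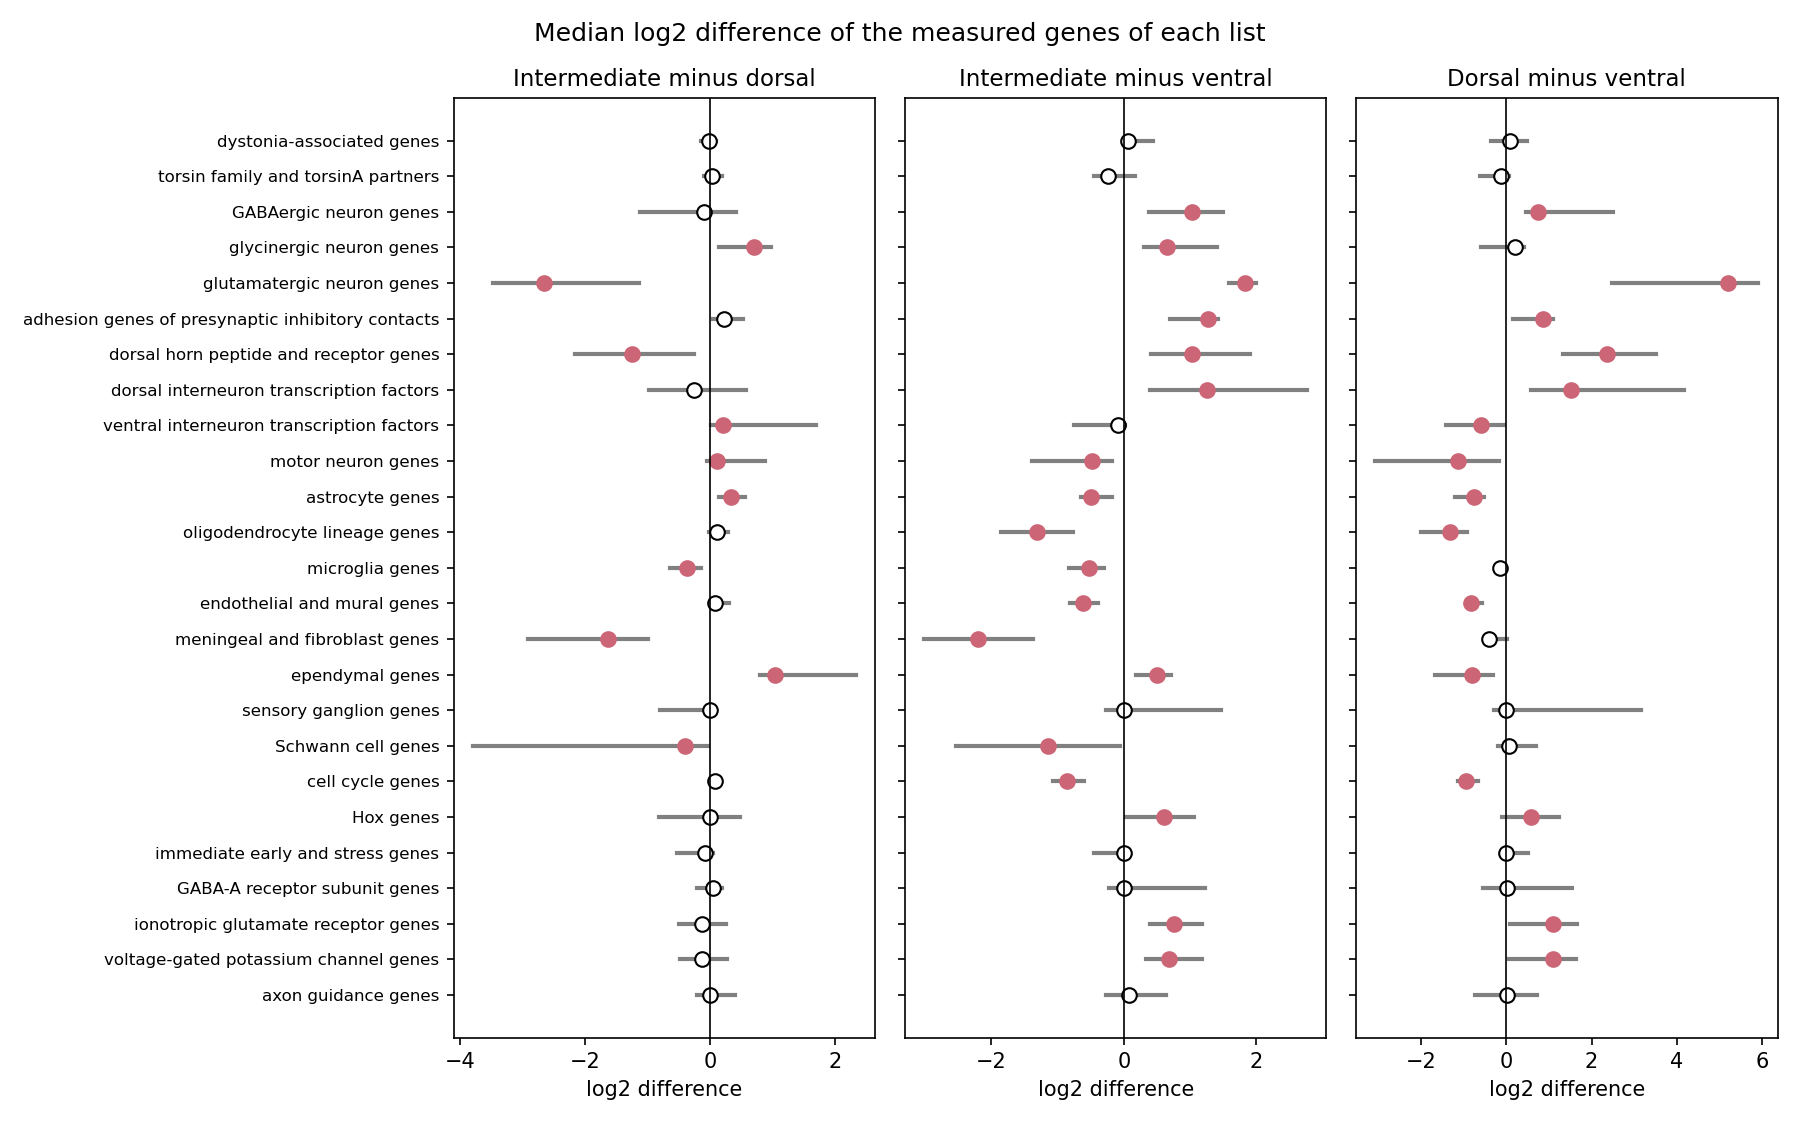
Median log2 difference of 25 gene lists (points, with bars from the lower to the upper quartile of their genes) for intermediate minus dorsal, intermediate minus ventral and dorsal minus ventral; filled red points are lists with a camera adjusted p under 0.05 at the preset correlation, open points the others. Glycinergic genes lay at 0.71 and 0.65 in the comparisons of the intermediate region, and meningeal and fibroblast genes at -1.63 and -2.20.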

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

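The test of the probe sets described here was chosen only after the data were seen. Of the 10092 probe sets with no gene symbol or with several, 5850 passed the same filter, barely above the floor, and were tested with the same model. None of the comparisons above uses them. Of these 5850, 904 (15.5%) differed between intermediate and dorsal pieces, 1212 (20.7%) between intermediate and ventral, and 1778 (30.4%) between dorsal and ventral. These shares were lower than the 30.1%, 48.2% and 52.8% of the genes with a symbol. In the intermediate region 101 unnamed probe sets were higher than in both others and 97 lower, and the one with the largest excess stood 2.38 above dorsal and 1.88 above ventral. The sequences they measure were not analysed here, and no explanation was tested.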

How the results depend on the processing

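The tests limited to genes with 9 distinct values, to genes with a mean of at least 6, and to genes outside the meningeal and Schwann cell lists were chosen only after the data were seen. Under 10 other choices of processing, fixed beforehand and fitted to all 9 arrays at the same threshold, and under these 3, each count of genes stayed within 1.5 times the reported one. The counts ranged from 3444 to 4762 genes between intermediate and dorsal pieces, 5044 to 7261 between intermediate and ventral, 5315 to 7772 between dorsal and ventral, 702 to 1230 higher than both, 430 to 688 lower than both (1230 and 430 both with arrays centred on their medians), 4152 to 5827 against the mean of the others, and 5979 to 8627 between any regions. The planned pseudocounts were not run, because the values were already logarithmic.

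A required log2 difference of at least 1 left, in the same order, 537, 1328, 1802, 51, 67, 368 and 2213 genes, since it is stricter by construction. Only the arrays of the 2 regions compared gave 2105 genes between intermediate and dorsal pieces, a fit with fewer samples. With the animal left out of the model, the counts were 4424, 6856, 7576, 959, 638, 5295 and 8365, and the pairwise ones shared 3946, 6501 and 7179 genes with the model that holds it.

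With 1 animal or array left out, the counts ranged from 1464 to 3707, 4200 to 6658, 5234 to 7125, 235 to 887, 175 to 535, 1477 to 5056 and 5046 to 7633, each lowest without animal 3, again with fewer samples. Further counts more than 1.5 times below the reported ones were, without animal 1, 1903 between intermediate and dorsal pieces, 365 higher than both, 211 lower than both and 2074 against the mean; without animal 2, 2454 between intermediate and dorsal, 298 lower than both and 3340 against the mean; without the third dorsal array, 381 lower than both; without the first intermediate array, 508 higher, 347 lower and 2919 against the mean; and without the third intermediate array, 553 higher and 3396 against the mean. The third array of a region comes from animal 3.

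Of 75 list tests, 43 passed as reported, 43 without the animal in the model, 42 with quantile normalisation and 41 with the mean of all probe sets, but 0 with an estimated correlation (14 at an unadjusted p under 0.05) and 66 with fry, which asks another question; the cause of the 0 was not tested.

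For the named genes, 4884 of 5016 values under other processing kept the direction and side of the threshold, 126 kept the direction alone and 6 reversed; with an animal or array left out these numbers were 3956 of 4488, 531 and 1. Of 342 values of other probe sets of these genes, 52 lay within a standard error of the reported one, 277 moved further and 13 reversed. The cause of the reversals was not tested. Other probe sets gave, for intermediate minus dorsal, -0.001 for Acta2, -0.057 for Cdh7, 0.051 for Chl1, -0.182 for Cntnap2 and -0.029 for Syne1. For intermediate minus ventral they gave -1.50 for Cntn1 (-0.337 for the mean of its probe sets), 0.013 for Mcm3, 0.313 for Sgce, 0.040 for Snapin and -0.018 for Syne2. For dorsal minus ventral they gave -0.523 for Kcnma1, 0.292 for Kif5b and 0.667 for Sgce (0.116 for the mean of its probe sets). The most variable probe set of Cntn1, Cntnap2 and Sgce was the one given here. Tor1a, which did not pass in any comparison, ranged between dorsal and ventral from -2.1e-05 without animal 1 to 0.11 without animal 3. Klhl14 kept its excess over both regions under all alternatives run here, from 2.94 to 3.17 over dorsal and 3.36 to 3.50 over ventral.

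Centring arrays on their medians shifted the median difference of all genes by 0.07 at most. About 36.0% of the probe sets of an array stood at the floor: at the floor in all regions no difference can be measured, and against a region at the floor only a bound is given.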

Other observations

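The gene families and the tests of surface tissue, of floored or tied values and of dilution below were chosen only after the values were seen, and the permutation p for microglia was added after its correlation was known. No family below passed Fisher's exact test for genes higher in the intermediate region. Of 9 serotonin receptor genes tested, 3 were higher than in both other regions: Htr2c by 1.49 ± 0.07 over dorsal and 1.53 over ventral, Htr1b by 2.87 ± 0.07 and 1.16, and Htr7 by 0.29 ± 0.04 and 1.08. Against dorsal and ventral, 3 and 4 of the 9 were higher and 0 lower (adjusted p = 0.435 and 0.516). Of 3 cerebellin genes 1 was higher and 2 lower than in dorsal pieces (adjusted p = 0.702 and 0.364), and 3 were higher than in ventral (adjusted p = 0.18); Cbln4 was higher than in both, by 2.86 ± 0.09 and 1.27. Of 16 synaptotagmin genes 5 were higher and 7 lower than in dorsal pieces (adjusted p = 0.435 and 0.113), and 7 higher and 1 lower than in ventral (adjusted p = 0.377 and 0.434), with Syt2 higher than in both by 2.37 ± 0.09 and 0.35. Of 40 collagen genes 9 were lower than in both regions, whereas Col19a1, Col24a1 and Col25a1 were higher than in both (adjusted p = 0.111 for lower genes against ventral). Of 47 cilia and flagella genes, 2 were lower against ventral, fewer than among other genes (adjusted p = 0.0244), and Spag1, Rsph4a, Cfap126, Tekt5 and Cfap54 were higher than in both.

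Genes lower in the intermediate region than in both others included meningeal and Schwann cell genes, and surface tissue, meaning meninges and nerve roots, in the dorsal and ventral pieces is a candidate explanation. Outside those lists, 575 genes of the pattern had a median correlation of 0.162 with the meningeal score of the arrays within regions. In 1000 random gene sets the median was -0.156, and all but the highest 25 lay under -0.097. Over all 9 arrays, 25.2% of the 575 genes correlated above 0.5, a share that was not computed for the random sets. Without the first dorsal array the median correlation was 0.065, against -0.023 and 0.032 in the random sets. Random sets draw genes singly over the same 9 arrays, whereas genes of the pattern may move together. Their limits therefore do not measure how the median would vary over animals, and these values cannot decide whether the pattern follows the score. The meningeal genes with the highest signal, Col3a1 and Col1a2 (signals of different probe sets do not rank abundance), fell from 12.9 and 12.7 in dorsal to 9.86 and 10.7 in intermediate pieces, and of the list 1 gene, Aldh1a2, is also on the motor neuron list. Floored or tied values were not the whole source, since 465 of the 586 genes had 9 distinct values above the floor. A fit to genes with 9 distinct values alone gave 553 lower than in both. The share was 6.93% of genes with 9 distinct values, against 4.20% of all genes. Genes at the floor on all arrays cannot be called, which lowers the share of all genes, so these shares decide nothing further. A difference in the cells of the cord itself stays open and was not tested.

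Genes higher in the intermediate region than in both others could reflect dilution, if less surface tissue there raised all other transcripts alike. Of 23 genes of the GABAergic, glycinergic and glutamatergic lists, 10 were lower in intermediate than in dorsal pieces and 10 higher. A common rise alone therefore does not account for the differences within these lists. The lower genes are by definition outside the set higher than in both, so these values cannot decide whether dilution raised that set. Floored or tied values were not the whole source here either. Of the 873 genes higher than in both, 669 had 9 distinct values, and a fit to such genes alone gave 762. Neither value covers the other genes. The share was 9.97% of genes with 9 distinct values, against 6.25% of all genes. These shares decide nothing further, because genes at the floor on all arrays cannot be called. A difference between the cells of the regions stays open and was not tested.

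Microglia genes lower than in both regions may come from the same surface tissue. The mean deviation of the 9 genes within regions correlated with the meningeal score at 0.599 over the 9 arrays (exact permutation within regions, p = 0.301 over 216 permutations; rank correlation 0.567, p = 0.255). Without the first dorsal array the correlation was 0.888, and without the first and second it was 0.683. The 9 arrays are too few to decide, and this origin and a difference in microglia between the regions cannot be told apart.

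Other splits of the arrays were also fitted. For the 3 pairwise comparisons the real splits gave 4202, 6731 and 7364 genes and the highest of the others 0 in each; 1 of the 10 splits gave as many genes, and 10 splits are too few for a share under 0.05. Of 100 drawn splits of the 9 arrays, 2 gave as many genes higher than both (873, with 1751 in the highest other) and 2 as many lower than both (586 and 1449). The real split alone gave as many against the mean of the others (5127 and 5083) and between any regions (8101 and 3927). The other split with so many genes higher and lower than both put the 3 ventral arrays in the intermediate place and mixed the dorsal and intermediate ones, a structure of the samples. These shares were under 0.05. However, the drawn splits other than the real one mixed arrays of different regions, which widens the spread within groups and leaves few calls. They show that the arrays group by region, and cannot show that these 4 counts are particular to the intermediate region. Among splits that keep each animal's arrays apart, 4, 4 and 3 of 100 gave as many for the first 3 counts. Each case included the real split and 2 with whole regions renamed. With the ventral arrays in the intermediate place, 2822 genes were higher than both, 2502 lower than both and 7487 differed from the mean of the others. With the dorsal arrays in that place these counts were 1395, 1442 and 6453. By these counts the real intermediate region had the fewest genes of the 3 regions. For the count between any regions, 1 of 36 splits, the real one, gave as many. The highest others without renamed regions gave 2011, 1682, 4846 and 3835 genes.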
